A study of Sus scrofa with 20 samples.

How the data were processed

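RNA from epicardial adipose tissue of Ossabaw pigs was sequenced in 20 libraries, of which 8 came from pigs on the Western diet with atorvastatin (WD+S), 6 from pigs on the Heart Healthy diet with atorvastatin (HHD+S) and 6 from pigs on the Heart Healthy diet alone (HHD). Groups were taken from the diet label of each library. That label calls the first group atherogenic, which was read as the Western diet of the series design. The design names 32 pigs, 16 of them boars and 16 gilts, in 4 groups, and the Western diet group without atorvastatin was not analysed here. A test of the interaction of diet with statin therefore could not be made. The labels give no sex, litter or batch per library, and replicate numbers follow the order of deposit, so no samples were paired. Libraries within a group were treated as separate animals because their titles carry different numbers, and if some shared an animal the p-values would measure technical spread in part.

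Per the labels' protocols, RNA was extracted with a column kit, treated with DNase and sequenced only where its quality indicator exceeded 7, and libraries were made after mRNA purification with a kit (TruSeq RNA v2) that does not mark strand. Reads of overlapping or antisense genes therefore cannot be told apart. Per the submitters' processing notes, bcl2fastq 2.17.1.14 and the Sscrofa10.2 build were used. The aligner, the counting program and the treatment of reads mapping to several places are not given in the sources used here.

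The authors deposited 2 tables per library. The first holds whole-number counts, headed unique exon reads, per Sscrofa10.2 gene with 22861 rows, and was used for all main results. The second holds counts headed unique gene reads and, per the file headers, RPKM values for 10157 gene names, a different gene set whose origin is not stated. The authors' RPKM values entered no test. The second table's counts were used for a repeat of every test and for genes absent from the first. Of the rows of the first table, 6101 carried only an Ensembl ID. A reference list of gene names gave 890 of them a symbol, which left 5211 with an ID only. Another 2891 rows have a name with a copy number, such as ABCA1_1 (one of 2 rows named for ABCA1). Reads of such genes, of the pig MHC genes (SLA) and of other multigene families may be split between rows, so their values are uncertain. The tables carry no coordinates, and positions were not analysed here.

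Counts in the first table summed to between 2749337 and 6543337 per library with a median of 3849195.5. One count was thus worth less than 1 CPM in every library, and genes below a few CPM were measured on few reads. The file names carry a pool number (1 or 2), a preparation code and a letter, none of which the labels give apart from a B that ends the title of HHD+S replicate 6. Pool 1 held 4 libraries of each group. Pool 2 held 4 WD+S, 2 HHD+S and 2 HHD libraries. The letter was B for 1 HHD and 2 HHD+S libraries. What these marks stand for is not stated, and the pool was treated as a possible batch. The 2 tables of each library were kept apart and never merged.

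Genes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test on the counts as deposited, with TMM scaling, the tool's own expression filter (minimum count 10, minimum total 15) and one fit over all 20 libraries, so that the groups shared one dispersion estimate. The filter left 11366 genes in the first table and 6685 in the second. Values of p were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison, with a threshold of 0.05. A standard error of a log2 fold change was computed as its size over the square root of F and is approximate. Levels are given as CPM on TMM-scaled library sizes, as mean ± SD over the libraries of a group. Levels of XIST and of the Y-linked genes are instead CPM on library totals without TMM scaling.

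Before the data were examined, 32 lists of genes were fixed for pathways, cell types that a dissection of this fat could hold, and tissue handling. Of these, the list of Y-linked genes served only as a covariate, and 29 of the others had at least 5 tested members. Each list was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 87 tests of 29 lists in 3 comparisons. The list tests were repeated with an estimated correlation and with fry, which asks whether a list's genes move, on balance, in one direction. The list score of a library is the mean log2 CPM of the members, and differences in it were also taken without each library in turn, a step chosen after the data were seen. Scores were compared between groups by two-sided exact permutation over all splits, within each pool and within pools jointly, with adjustment over the same 87 tests for the first. Mean fold changes of lists come from these log2 CPM and those of single genes from edgeR, which models the mean of the counts rather than of their logarithms, so the 2 can differ where libraries of a group vary widely. Members were also counted as past the threshold when adjusted over the list alone.

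The genes named in the text follow a rule fixed in advance. As no gene passed in the edgeR fit of all libraries in any comparison, they are the 10 with the smallest p per comparison that have a symbol and a mean log2 CPM of at least 1, up to 4 members with the smallest p of each list whose test passed, and a fixed set of genes that includes SQLE, MX1, ISG15, CXCL10, ADIPOQ and LEP where measured. Some results of this rule, and of 1 list, are not reported here. ISG15 and ADIPOQ were read from the second table. Genes named for another reason are said to have been chosen after their values were seen.

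The gene and list tests were tested on simulated data drawn from the real means, dispersions and library sizes with 200 changed genes. Of simulated 2-fold changes in WD+S against HHD, 57.4% of 61 genes were recovered among 11295 tested, and of 4-fold changes 100% of 68. The corresponding shares of 2-fold changes were 78.7% of 61 for WD+S against HHD+S (11279 genes tested) and 69.4% of 62 for HHD+S against HHD (11291 tested). A 1.5-fold change was recovered in 33.8%, 34.3% and 37.1% of the genes given it, for WD+S against HHD+S, HHD+S against HHD and WD+S against HHD. A simulated rise of the endothelial list by 1.5-fold was called in all 3 comparisons with either correlation, and no other list was called with the preset correlation. Genes were drawn independently of each other, so the simulation cannot show how the list tests fare where members of a list vary together. It also holds no libraries that stand apart in many genes at once, and its shares apply to 200 changed genes. In the real data RSAD2 differed by more than 4-fold in HHD+S and in WD+S against HHD. It was not called by edgeR in the fit of all libraries. A lack of calls therefore does not show that 4-fold changes were absent. Alternatives were DESeq2 1.42.0, limma-voom with quality weights, DESeq2 size factors, 2 other filters, fits of the 2 compared groups only, the second table, the pool, the Y-linked level or the cardiomyocyte level as a term, fits within each pool, fits without the libraries marked B and fits without each library in turn. The 3 comparisons share libraries, so no correlation or overlap between them was computed. Pseudocounts planned for a table without counts were not tried, because both tables hold counts. Each count of genes, each count of lists and each mean of the interferon list was also compared with 100 splits of the same libraries.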

Results

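Epicardial adipose tissue, the fat depot that lies directly on the heart muscle, was profiled by RNA sequencing in Ossabaw pigs, a miniature breed prone to obesity and metabolic disease. The 20 libraries fell into 3 groups. Pigs of the WD+S group (n = 8) ate a diet rich in saturated fat, cholesterol and refined grain and received atorvastatin, a drug that inhibits cholesterol synthesis. Pigs of the HHD+S group (n = 6) ate a diet rich in unsaturated fat, whole grain, fruit and vegetables with the same drug, and those of the HHD group (n = 6) ate that diet alone. Library depth ran from 2749337 to 6543337 counts. The series title names interferon signalling in this fat after the Western diet and atorvastatin, so interferon-induced genes were examined in each comparison.

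Sex is not in the labels of single libraries, so reads of XIST, the RNA that silences an X chromosome in females, and of 4 Y-linked genes were counted in the second table; XIST was chosen after its values were seen. On library totals without TMM scaling, XIST stood between 813.6 and 1300 CPM in 11 libraries with at most 2 Y-linked reads. In 7 the Y-linked genes stood between 272.6 and 335.1 CPM with at most 10 XIST reads. The 7 were WD+S replicates 3, 5, 7 and 8, HHD+S replicates 3 and 5 and HHD replicate 6. By these reads the groups were not balanced for sex. The Y-linked level was used as a term for single genes and the interferon list only. An effect of sex on the other lists, the neural list among them, was not tested. HHD replicates 3 and 5 carried both, with 1437 XIST and 813 Y-linked reads in replicate 3 and 3396 and 147 in replicate 5. Without these libraries the mean log2 fold change was 1.11 for the interferon list HHD+S vs HHD and 1.15 for the interferon list WD+S vs HHD.

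**Figure D1:**
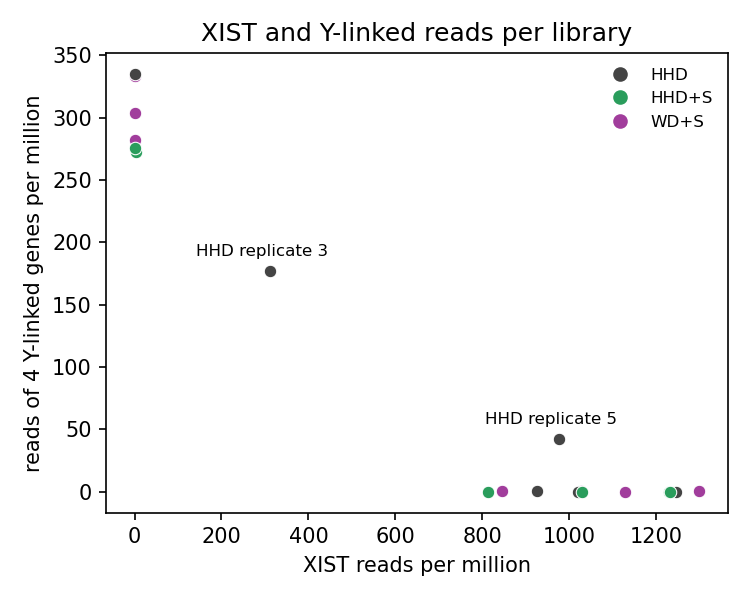
CPM, without TMM scaling, of XIST (horizontal axis) and of 4 Y-linked genes together (vertical axis) in the second table, with one point per library, coloured by group. HHD replicate 3 lies at 312.8 and 177.0 CPM and HHD replicate 5 at 977.4 and 42.3.

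The comparison of HHD+S with HHD asks what atorvastatin does on the Heart Healthy diet. The interferon list had a higher mean in HHD+S, but by very different amounts from library to library. The antiviral gene RSAD2 (ENSSSCG00000008648) averaged 46.0 ± 60.3 CPM in HHD+S and 3.33 ± 1.72 CPM in HHD (SD, n = 6 each), a log2 fold change of 3.80 (SE 0.87, edgeR adjusted p = 0.40). RSAD2 stood at 127.5 and 120.1 CPM in HHD+S replicates 5 and 6, both of pool 2, and between 5.79 and 8.25 CPM in the remaining HHD+S libraries. The chemokine CXCL10 followed the same split, with 200.8 and 372.3 CPM in these libraries and at most 6.32 CPM in the other HHD+S libraries, against 4.30 ± 2.704 CPM in HHD (n = 6).

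No gene of 11366 passed the edgeR threshold for HHD+S against HHD, and the lowest adjusted p was 0.40. At an unadjusted p under 0.05 there were 960 genes, 536 higher and 424 lower, where 568 would be expected by chance. DESeq2 called 11 genes (8 higher, 3 lower) and limma-voom none. All 37 tested interferon-induced genes had a positive fold change, with a mean log2 fold change of 1.03 (camera adjusted p = 3.5e-18 with the preset correlation). This call did not hold with an estimated correlation (adjusted p = 0.66 with an estimated correlation). Of the 37 genes edgeR called 0 when adjusted over all genes and DESeq2 called RSAD2 and CXCL10, and 32 were higher in edgeR when adjusted over the list alone. Their mean of the edgeR fold changes was 1.58. By list score HHD+S exceeded HHD by 1.03 (exact permutation p = 0.0065, adjusted p = 0.23), and 5 of 6 HHD+S libraries scored above all HHD libraries. Within pool 1 the difference was 0.26 (exact permutation p = 0.057, 4 against 4, smallest possible p 0.029), and within pool 2 it was 2.58 (2 against 2, exact permutation p = 0.33, the smallest possible). OAS1, which makes the activator of RNase L, averaged 207.8 ± 184.7 CPM in HHD+S and 53.5 ± 13.5 CPM in HHD. The corresponding means were 74.0 ± 85.5 and 12.6 ± 2.47 CPM for XAF1, and 411.8 ± 607.7 and 38.2 ± 5.43 CPM for GBP1 (SD, n = 6 each). MX1, an antiviral GTPase, had a log2 fold change of 2.00 (SE 0.60, edgeR adjusted p = 0.40). The ubiquitin-like gene ISG15, measured in the second table, averaged 193.4 ± 258.3 CPM in HHD+S against 19.4 ± 6.17 CPM in HHD (log2 fold change 3.32, SE 0.88, edgeR adjusted p = 0.34).

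**Figure D2:**
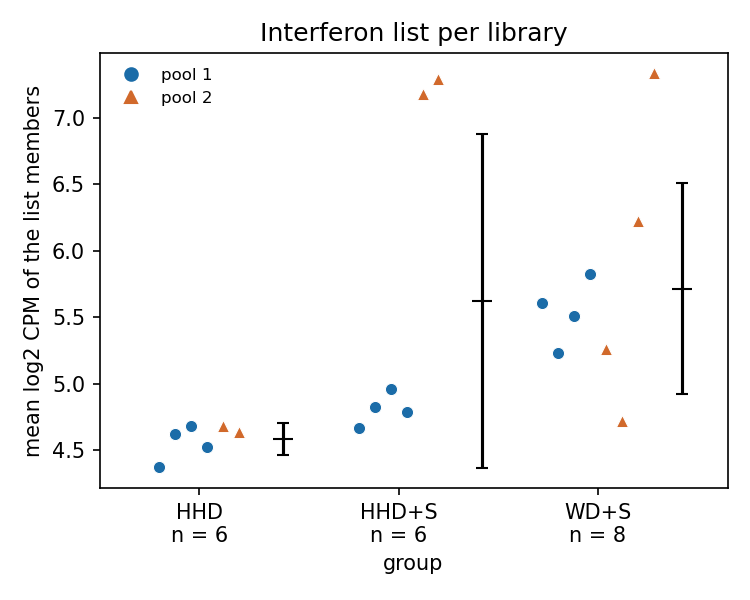
Interferon list score of each library, the mean log2 CPM of the 37 tested members, by group; circles are libraries of pool 1, triangles of pool 2, and black bars the mean ± SD. The 6 HHD libraries lie between 4.37 and 4.68, and the scores of HHD+S replicates 5 and 6 are 7.18 and 7.29.

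The MHC class I and T cell lists were called with the preset correlation but not with an estimated one. The 11 tested MHC class I genes had a mean log2 fold change of 0.48 in HHD+S against HHD (camera adjusted p = 0.00023). This became an adjusted p = 0.66 with an estimated correlation, and 6 members were higher when adjusted over the list alone. By list score the difference was 0.05 within pool 1, 1.34 within pool 2 and 0.29 without HHD+S replicate 6. The proteasome activator PSME2 averaged 114.7 ± 80.6 CPM in HHD+S and 49.7 ± 11.3 CPM in HHD (n = 6 each), and the class I heavy chain genes SLA-5 and SLA-8 had log2 fold changes of 1.03 and 0.56. For the 7 T and NK cell genes the mean was 0.74 (camera adjusted p = 0.020; adjusted p = 0.80 with an estimated correlation), with 4 higher when adjusted over the list alone. From the edgeR fold changes it was 1.35. By list score it was -0.36 within pool 1 and 2.94 within pool 2, and 0.44 and 0.34 without HHD+S replicate 5 or 6. The chemokine CCL5 reached 50.1 and 120.1 CPM in HHD+S replicates 5 and 6 and at most 8.23 CPM in the other HHD+S libraries. CD8A, a chain of the CD8 co-receptor, reached 20.5 and 34.7 CPM in the same libraries, and LCK and CD2 had log2 fold changes of 1.73 and 1.72. These 2 libraries stood apart in other cell lists too, seen after the fact. Their macrophage scores were 6.15 and 6.62 against at most 5.40 in the other HHD+S libraries, their B and plasma cell scores 4.30 and 4.54 against at most 3.12, and their MHC class II scores 7.70 and 8.13 against at most 6.83. Their erythroid scores were 1.58 and 3.31 against at least 4.62. HHD replicate 2 had higher macrophage and B and plasma cell scores than either, 7.01 and 6.15, with an interferon score of 4.62. Among the 10 genes with the smallest p, none of which passed in edgeR, were GBP6_3 and the NK cell gene NKL, with log2 fold changes of 3.87 (SE 0.94) and 3.62 (SE 0.88).

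The connective tissue lists had lower means in HHD+S than in HHD, with few members past a threshold. The 28 fibroblast and matrix genes had a mean log2 fold change of -0.37 (camera adjusted p = 9.0e-07; adjusted p = 0.66 with an estimated correlation), and 3 were lower when adjusted over the list alone. COL3A1, the chain of fibrillar collagen III, averaged 7846 ± 3614 CPM in HHD+S and 14665 ± 2302 CPM in HHD (SD, n = 6 each; log2 fold change -0.90, SE 0.29, edgeR adjusted p = 0.40), with 5 of 6 HHD+S libraries below every HHD library. POSTN and COL5A2 had log2 fold changes of -1.07 (SE 0.27) and -0.52 (SE 0.14), and COL1A1 one of -0.88 (SE 0.30). The list score was lower by -0.37 overall (exact permutation p = 0.017, adjusted p = 0.34), by -0.27 within pool 1 and by -0.55 within pool 2. The 15 mesothelial genes had a mean of -0.87 (camera adjusted p = 0.0016; adjusted p = 0.66 with an estimated correlation), with 3 lower and 1 higher when adjusted over the list alone; by list score it was -1.04 within pool 1 and -0.54 within pool 2. The retinoic acid enzyme ALDH1A2 averaged 12.6 ± 2.95 CPM in HHD+S and 25.3 ± 8.82 CPM in HHD, and BNC1 and PKHD1L1 were lower by -3.26 and -1.17 on the log2 scale. The protease inhibitor SLPI, of the same list, went the other way, at 100.8 ± 40.8 CPM against 50.9 ± 12.5 CPM (n = 6 each). The 18 cell cycle genes had a mean of -0.33 (camera adjusted p = 0.017; adjusted p = 0.80 with an estimated correlation), which rested largely on HHD replicate 2. By list score it was -0.10 without that library, -0.64 within pool 1 and 0.29 within pool 2. KIF11 and CCNB1, both of mitosis, had log2 fold changes of -1.27 and -1.22. HHD replicate 2 carried 17.2 CPM of KIF11 where the HHD+S libraries ranged from 1.54 to 4.64 CPM.

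Genes of cholesterol synthesis, which depend on the sterol level of the cell, differed little. The 24 tested members had a mean log2 fold change of 0.18 in HHD+S against HHD, 20 of them positive (camera adjusted p = 0.0024). This was an adjusted p = 0.80 with an estimated correlation, and 0 members passed when adjusted over the list alone. By list score the difference was 0.36 within pool 1 and -0.17 within pool 2. FDPS averaged 103.9 ± 14.6 CPM in HHD+S and 78.5 ± 15.3 CPM in HHD (SD, n = 6 each). SQLE had a log2 fold change of 0.21 (SE 0.22), and TM7SF2, IDI1 and INSIG1 had changes between 0.33 and 0.48. The respiratory chain and ribosomal protein lists had means of 0.15 each (camera adjusted p = 0.00098 and 6.8e-05), and both reached an adjusted p = 0.80 with an estimated correlation. NDUFAB1 and RPL18, of these lists, had log2 fold changes of 0.36 and 0.25, and 0 members of either passed when adjusted over the list alone. In HHD replicate 3 both list scores were far below those of the other HHD libraries, at 6.54 against at least 7.18 and at 8.52 against at least 9.26. Without that library both differences in list score fell to 0.02. With it they were 0.25 and 0.22 within pool 1 and -0.06 and 0.02 within pool 2. The remaining genes with the smallest p were ANKRD6 (ENSSSCG00000004322), lower in all 6 HHD+S libraries than in any HHD library (log2 fold change -1.15, SE 0.24), PTN, CMTM5, TAF1D and NLGN2. PTN, a heparin-binding growth factor, stood at 147.1 and 93.9 CPM in HHD replicates 1 and 2 and at 7.45 to 12.8 CPM in the other HHD libraries.

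The comparison of WD+S with HHD+S asks what the Western diet does in pigs on atorvastatin. The neural and cardiomyocyte lists had higher means in WD+S, and the adipocyte, endothelial and lysosomal lists lower ones, all called with the preset correlation but not with an estimated one. TUBB3, the neuronal tubulin, averaged 569.8 ± 180.1 CPM in WD+S (n = 8) and 324.7 ± 142.4 CPM in HHD+S (n = 6), and the peripheral neuron filament PRPH 356.4 ± 119.9 and 200.02 ± 83.8 CPM. ANKRD6, an ankyrin repeat gene, was higher in all 8 WD+S libraries than in any HHD+S library, at 6.32 ± 0.850 against 2.53 ± 0.851 CPM (log2 fold change 1.29, SE 0.23, edgeR adjusted p = 0.12). ABCA1_1 (ENSSSCG00000026173), one of the rows named for the cholesterol exporter ABCA1, was also higher in all 8 libraries, at 109.0 ± 5.14 against 63.3 ± 12.6 CPM (log2 fold change 0.78, SE 0.17, edgeR adjusted p = 0.23).

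No gene of 11366 passed the edgeR threshold for WD+S against HHD+S, where 988 genes (671 higher, 317 lower) had an unadjusted p under 0.05 and 568 would be expected by chance. DESeq2 called 10 genes (8 higher, 2 lower) and limma-voom with quality weights 4, which were ABCA1_1, ANKRD6, MFNG and DKK3. Of the 10 genes with the smallest p, the Notch modifier MFNG and the retinol carrier RBP4 were lower, at 88.7 ± 6.22 against 133.2 ± 25.8 CPM and at 85.5 ± 21.7 against 148.7 ± 52.2 CPM. TMOD1, CEL, NLGN2, DPYSL3_2, DISP2 and DKK3 were higher, with log2 fold changes between 0.63 and 1.77. Each of the 10 missed the threshold in the edgeR fit of all libraries. All but CEL and NLGN2 were among the DESeq2 calls, MFNG passed in edgeR without HHD+S replicate 2 (edgeR adjusted p = 0.013), and ABCA1_1 in a fit of the 2 groups (edgeR adjusted p = 0.021).

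**Figure D3:**
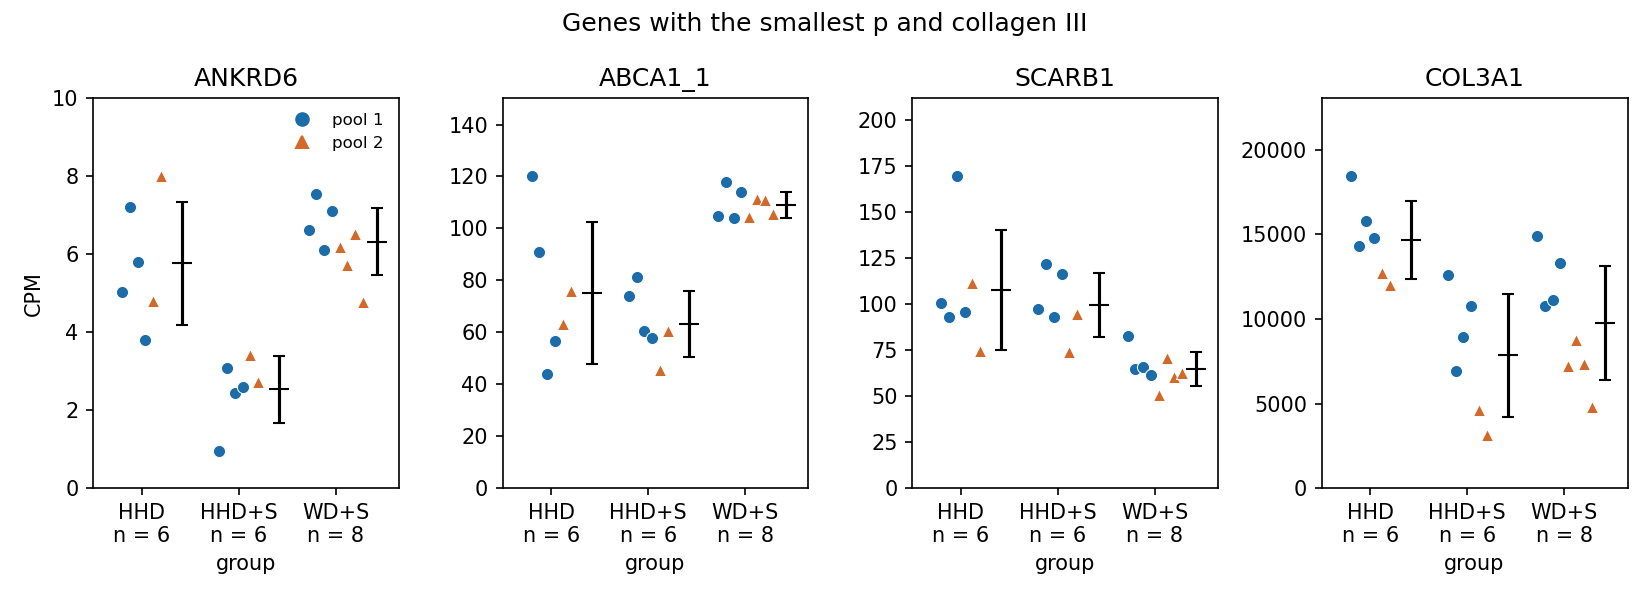
CPM per library of ANKRD6, ABCA1_1, SCARB1 and COL3A1 by group, with circles for pool 1, triangles for pool 2 and bars for the mean ± SD; axes start at 0. The WD+S libraries hold 104.0 to 117.8 CPM of ABCA1_1, above the highest HHD+S library at 81.4 CPM.

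The 16 neural genes had a mean log2 fold change of 0.58 in WD+S against HHD+S, 16 of them positive (camera adjusted p = 3.4e-07; adjusted p = 0.66 with an estimated correlation), and 8 were higher when adjusted over the list alone. PHOX2A, a regulator of autonomic neurons, and CHGB, of their secretory granules, had log2 fold changes of 1.09 (SE 0.31) and 0.81 (SE 0.29). The list score was higher by 0.58 (exact permutation p = 0.021, adjusted p = 0.34), by 0.33 within pool 1 and by 0.93 within pool 2. The 22 cardiomyocyte genes had a mean of 1.31, with 21 positive (camera adjusted p = 1.8e-07; adjusted p = 0.66 with an estimated correlation) and 0 past the threshold when adjusted over the list alone. Levels varied widely, with atrial myosin light chain MYL7 at 15.8 ± 21.5 CPM in WD+S and 0.760 ± 0.643 CPM in HHD+S, and the heavy chain MYH6 between 10.8 and 315.5 CPM in WD+S. MYL4 and ACTN2 had log2 fold changes of 4.02 (SE 1.31) and 1.34 (SE 0.53). WD+S replicate 5 held 429.6 CPM of ACTN2, against at most 168.9 CPM in the other WD+S libraries. The cardiomyocyte score was higher by 1.31 (exact permutation p = 0.089), by 1.45 within pool 1 and by 0.78 within pool 2.

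**Figure D4:**
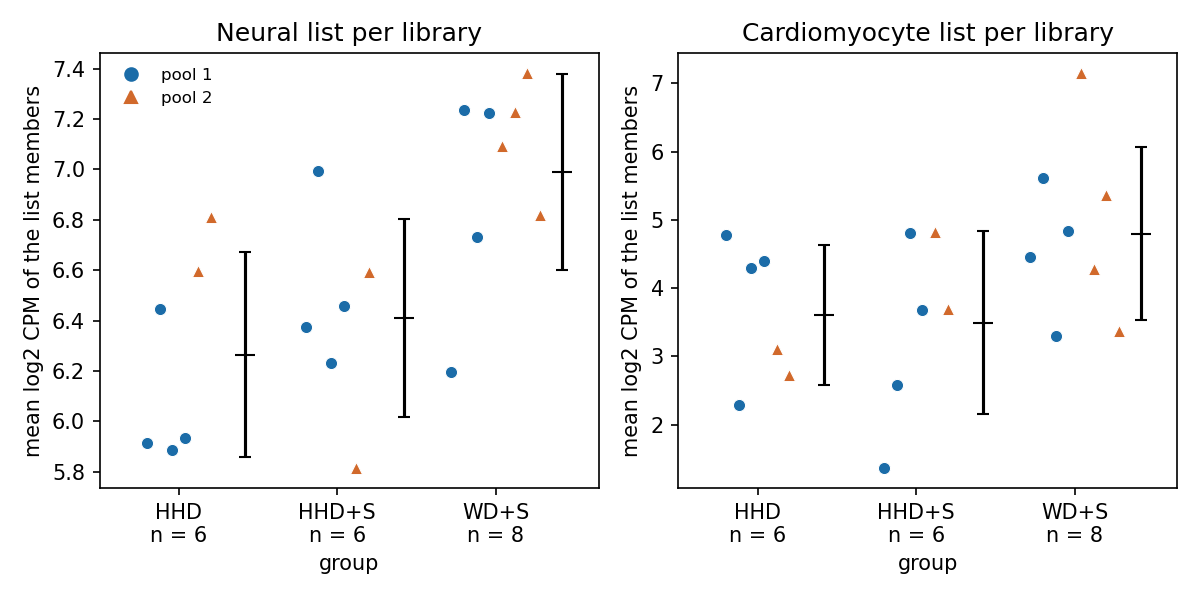
Scores of the neural list (left) and the cardiomyocyte list (right) per library by group, as mean log2 CPM of the members; circles are pool 1, triangles pool 2, bars the mean ± SD. The neural scores average 6.99 in WD+S, 6.41 in HHD+S and 6.26 in HHD.

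Among the lower lists, the 12 adipocyte genes had a mean log2 fold change of -0.29 (camera adjusted p = 0.0022; adjusted p = 0.66 with an estimated correlation), with 2 lower when adjusted over the list alone. The list score differed by -0.39 within pool 1 and by -0.21 within pool 2. PPARG, the master regulator of fat cell differentiation, averaged 124.0 ± 17.0 CPM in WD+S (n = 8) and 171.7 ± 28.4 CPM in HHD+S (n = 6), and GPD1 and PLIN1 had log2 fold changes of -0.55 and -0.39. The hormone genes LEP and ADIPOQ had changes of -0.67 (SE 0.33) in the first table and -0.30 (SE 0.19) in the second. The 19 endothelial genes had a mean of -0.19 (camera adjusted p = 0.0022; adjusted p = 0.66 with an estimated correlation), with 1 lower when adjusted over the list alone. By list score it was -0.02 within pool 1 (exact permutation p = 0.83) and -0.42 within pool 2 (exact permutation p = 0.067). ENG, a TGF-beta co-receptor of endothelium, averaged 282.1 ± 31.996 CPM in WD+S and 398.6 ± 54.2 CPM in HHD+S, and PECAM1 825.6 ± 88.9 and 1034 ± 117.0 CPM, each with 7 of 8 WD+S libraries below every HHD+S library. The 13 lysosomal and lipid-associated macrophage genes had a mean of -0.17 (camera adjusted p = 0.0035; adjusted p = 0.60 with an estimated correlation) and 0 past the threshold when adjusted over the list alone; by list score it was -0.21 within pool 1 and -0.16 within pool 2. The lysosomal cholesterol transporters NPC1 and NPC2 had log2 fold changes of -0.34 (SE 0.11) and -0.29 (SE 0.12). The 7 T and NK cell genes had a mean of -0.73 from log2 CPM and of -1.24 from the edgeR fold changes (camera adjusted p = 0.0032; adjusted p = 0.70 with an estimated correlation), and the difference was 0.15 by list score within pool 1 and -2.48 within pool 2, where HHD+S replicates 5 and 6 stand. Without either it was -0.43 or -0.33. Lists for the unfolded protein response (22 genes, CALR lowest in p at -0.32) and for fatty acid oxidation (18 genes, ACADL at -0.23) had means of -0.10 and -0.11 (camera adjusted p = 0.033 and 0.041). Both reached an adjusted p = 0.80 with an estimated correlation, with 0 members past the threshold adjusted over the list alone. By list score the first was -0.01 within pool 1 and -0.22 within pool 2, and -0.06 without WD+S replicate 5 or HHD+S replicate 6. Fatty acid oxidation turned between the pools, at -0.32 (exact permutation p = 0.057) and 0.19 (exact permutation p = 0.40). It was -0.06 without WD+S replicate 2 or HHD+S replicate 4, -0.07 without HHD+S replicate 3 and 0.02 in the second table (camera adjusted p = 0.58).

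The interferon list was not called between WD+S and HHD+S over all libraries, with a mean log2 fold change of 0.09 from log2 CPM, 24 of 37 positive (camera adjusted p = 0.81), and one of -0.20 from the edgeR fold changes, 10 of 37 positive. Within pool 1 the list score was higher in WD+S by 0.73, with every WD+S library above every HHD+S library (exact permutation p = 0.029, 4 against 4, the smallest possible). Within pool 2 it was lower by -1.35 (exact permutation p = 0.27, 4 against 2). RSAD2 was called by edgeR within pool 1 alone (log2 fold change 2.49, SE 0.26), the single gene so called. MX1 averaged 294.2 ± 286.1 CPM in WD+S and 292.6 ± 305.8 CPM in HHD+S, CXCL10 had a log2 fold change of -1.69 (SE 0.95) and ISG15 one of 0.02 (SE 0.73). The CXCL10 value rested on few libraries, with 200.8 and 372.3 CPM in HHD+S replicates 5 and 6 and 165.3 CPM in WD+S replicate 8. The other WD+S libraries held at most 26.7 CPM. Cholesterol synthesis genes had a mean of -0.01 by list score (exact permutation p = 0.97), which was -0.22 within pool 1 and 0.27 within pool 2 (exact permutation p = 0.34 and 0.13) and 0.09 without WD+S replicate 1. SQLE stood at -0.04 (SE 0.20).

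The comparison of WD+S with HHD changes diet and drug together. The interferon list had a higher mean in WD+S in both pools, and so had the neural list. RSAD2 ranged from 8.35 to 139.9 CPM in the 8 WD+S libraries and from 1.54 to 5.92 CPM in the 6 HHD libraries (log2 fold change 3.90, SE 0.85, edgeR adjusted p = 0.22). OAS1 and MX1 were also higher in all 8 WD+S libraries than in any HHD library, at 192.7 ± 131.1 against 53.5 ± 13.5 CPM and at 294.2 ± 286.1 against 72.9 ± 12.8 CPM (SD, n = 8 and 6). The leptin gene LEP averaged 13.8 ± 7.14 CPM in WD+S and 29.5 ± 14.7 CPM in HHD (log2 fold change -1.11, SE 0.32, edgeR adjusted p = 0.22).

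No gene of 11366 passed the edgeR threshold for WD+S against HHD in the fit of all libraries, with 1299 genes (859 higher, 440 lower) at an unadjusted p under 0.05 and 568 expected by chance. DESeq2 called 81 genes, 74 of them higher, and limma-voom none. The edgeR count was 22 without WD+S replicate 1 and 14 without HHD replicate 6. Of the genes named in this comparison, SLC8A2, SCARB1, SVOP, RAMP1, ADD2, NCAM1, BCAS4 and LEP were among the 22 (edgeR adjusted p from 0.043 to 0.049) and SCARB1, SVOP, RGMB and ALDH1A2 among the 14 (from 0.032 to 0.039). Within pool 1 (4 against 4) edgeR called 14 genes, all higher in WD+S, of which 12 belong to the interferon list: RSAD2, XAF1, OAS1, OAS2, IFIT3, PARP14, IFI44, IFIT1, MX1, CMPK2, IFIH1 and ZNFX1. The remaining genes were RIG-I and DDX60, and those of the 14 that the rule for named genes does not cover were chosen after their values were seen. Within pool 2 it called none.

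Of the 37 interferon-induced genes 36 were positive, with a mean log2 fold change of 1.13 in WD+S against HHD (camera adjusted p = 3.5e-18; adjusted p = 0.66 with an estimated correlation). Adjusted over all genes, edgeR called 0 of them in the fit of all libraries, 1 (RSAD2) in a fit of the 2 groups and 12 within pool 1, and DESeq2 called 6. In edgeR 26 were higher when adjusted over the list alone. All 8 WD+S scores lay above all 6 HHD scores, and the difference of 1.13 had an exact permutation p = 0.0017 (adjusted p = 0.14). It was 0.99 within pool 1 (exact permutation p = 0.029, the smallest possible) and 1.23 within pool 2 (exact permutation p = 0.20). HERC5 and IFI44 had log2 fold changes of 2.03 (SE 0.54) and 1.69 (SE 0.48). CXCL10 had one of 2.84 (SE 1.19) and ISG15, in the second table, one of 3.34 (SE 0.85). WD+S replicate 8 held 165.3 CPM of CXCL10, against at most 26.7 CPM in the other WD+S libraries. The T and NK cell score differed by 0.01 (exact permutation p = 0.98), by -0.21 within pool 1 and by 0.46 within pool 2, and by -0.16 without WD+S replicate 8 and 0.18 without HHD replicate 2. WD+S replicate 8 had the highest interferon score of its group, 7.34, and also the highest T and NK cell score, 3.38.

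**Figure D5:**
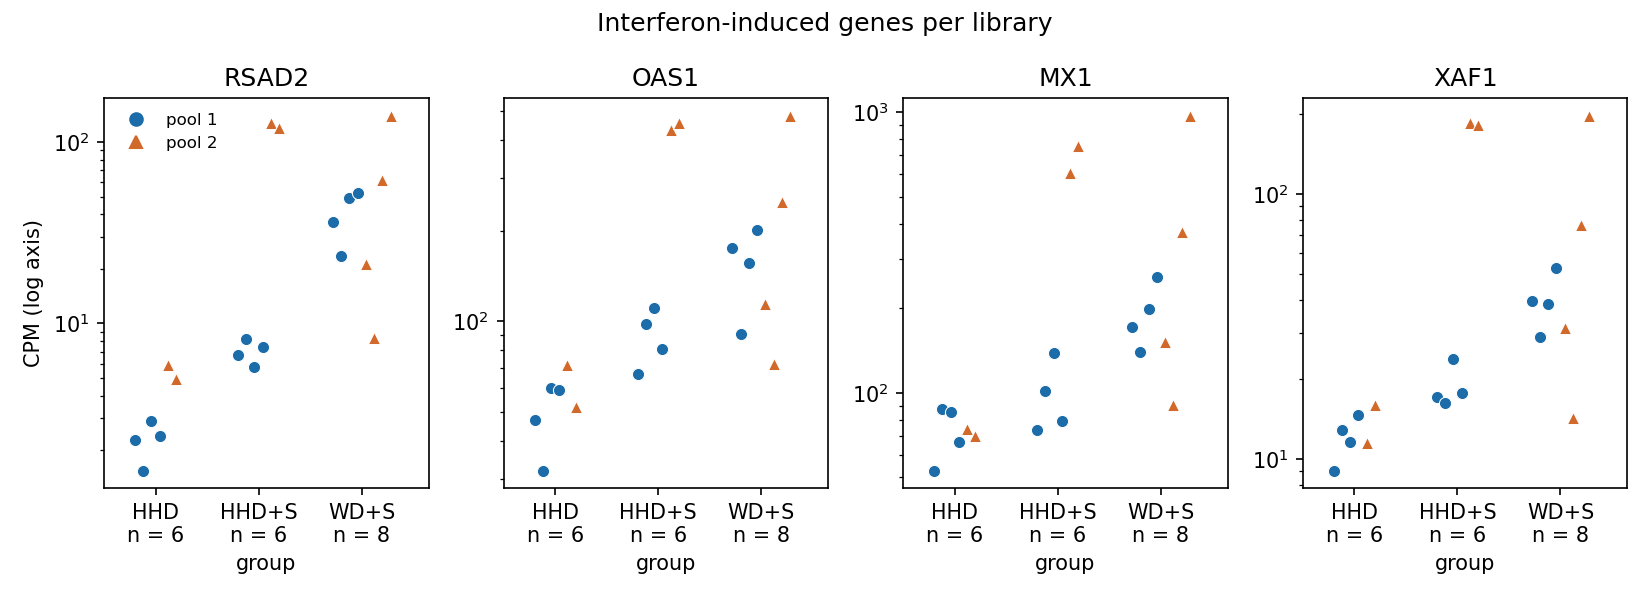
CPM of RSAD2, OAS1, MX1 and XAF1 in each library by group on a log axis, with circles for pool 1 and triangles for pool 2. For RSAD2 the HHD libraries lie between 1.54 and 5.92 CPM and the WD+S libraries between 8.35 and 139.9 CPM.

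All 16 neural genes were positive in WD+S against HHD, with a mean log2 fold change of 0.72 (camera adjusted p = 9.2e-11; adjusted p = 0.60 with an estimated correlation), and 12 were higher when adjusted over the list alone. TUBB3, CHGB, CHGA and the Schwann cell cadherin CDH19 had log2 fold changes of 1.03 (SE 0.28), 1.10 (SE 0.29), 0.72 (SE 0.21) and 0.68 (SE 0.19). The list score was higher by 0.72 (exact permutation p = 0.0080, adjusted p = 0.23), by 0.80 within pool 1 and by 0.42 within pool 2. Among the 10 genes with the smallest p, none of which passed in the edgeR fit of all libraries, SLC8A2, SVOP, RAMP1 and NCAM1 had log2 fold changes of 0.98, 1.34, 0.97 and 0.52, and SLC8A2, a sodium-calcium exchanger, was higher in all 8 WD+S libraries than in any HHD library. ADD2, BCAS4 and RGMB were also higher, by 1.45, 0.81 and 0.68. The cardiomyocyte list had a mean of 1.19 with 21 of 22 positive (camera adjusted p = 3.5e-06; adjusted p = 0.76 with an estimated correlation) and 0 past the threshold adjusted over the list alone. Its score differed by 0.61 within pool 1 and by 2.12 within pool 2 (exact permutation p = 0.079 overall). TNNC1 averaged 153.1 ± 151.4 CPM in WD+S and 42.6 ± 29.4 CPM in HHD, and ACTN2, CSRP3 and TRIM63 had log2 fold changes between 1.29 and 2.05. WD+S replicate 5 held the highest level of each of these genes.

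SCARB1 (ENSSSCG00000009759), the HDL receptor, averaged 64.8 ± 9.11 CPM in WD+S and 107.6 ± 32.6 CPM in HHD (log2 fold change -0.73, SE 0.15, edgeR adjusted p = 0.22), with 7 of 8 WD+S libraries below every HHD library. It leads the list of LXR targets and cholesterol efflux genes, whose 11 members had a mean of -0.17 (camera adjusted p = 0.029; adjusted p = 0.62 with an estimated correlation), with 2 lower when adjusted over the list alone. The score of the 11 differed by -0.19 within pool 1 and by -0.10 within pool 2. In the second table the mean was -0.03 (camera adjusted p = 0.60), with 7 of 13 positive and 2 higher and 2 lower when adjusted over the list alone. NPC1 and PLTP had log2 fold changes of -0.40 (SE 0.11) and -0.45 (SE 0.26), whereas ABCG1, also of this list, had one of 0.36 (SE 0.21). ABCA1_1, which is not a tested member, had one of 0.54 (SE 0.17). PLTP stood at 71.5 CPM in HHD replicate 2, against at most 37.4 CPM in the other HHD libraries. In WD+S replicate 1 it stood at 60.8 CPM, against at most 27.4 CPM in the other WD+S libraries. The 12 adipocyte genes were all negative, with a mean of -0.37 (camera adjusted p = 0.00068; adjusted p = 0.66 with an estimated correlation), and 1 was lower when adjusted over the list alone. The score differed by -0.52 within pool 1 and by -0.19 within pool 2. PPARG, CEBPA and PDE3B had log2 fold changes of -0.46, -0.48 and -0.33, and ADIPOQ one of -0.34 (SE 0.19). PPARG stood at 279.8 CPM in HHD replicate 4 and at most 183.5 CPM in the other HHD libraries. CEBPA stood at 126.9 and 140.9 CPM in HHD replicates 3 and 4 and at most 72.7 CPM in the others. HK2, a hexokinase, averaged 11.2 ± 2.38 CPM in WD+S and 25.2 ± 12.1 CPM in HHD. The 13 lysosomal genes had a mean of -0.14 (camera adjusted p = 0.020; adjusted p = 0.66 with an estimated correlation) with 1 lower when adjusted over the list alone (list score -0.20 within pool 1 and -0.07 within pool 2), although SPP1 of the same list had a log2 fold change of 0.54 (SE 0.26) beside -0.26 for LIPA and -0.49 for CTSL.

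The 28 fibroblast genes had a mean of -0.20 (camera adjusted p = 0.0011; adjusted p = 0.76 with an estimated correlation), with 1 lower when adjusted over the list alone, and the score differed by 0.06 within pool 1, by -0.43 within pool 2 and by -0.12 without WD+S replicate 8. COL5A2 was lower in all 8 WD+S libraries than in any HHD library, at 579.9 ± 83.1 against 818.9 ± 133.3 CPM. POSTN, COL6A3 and COL3A1 had log2 fold changes of -0.67, -0.51 and -0.59. The mesothelial list had a mean of -0.77 (camera adjusted p = 0.0021; adjusted p = 0.66 with an estimated correlation), with 1 lower when adjusted over the list alone; by list score it was -0.34 within pool 1 and -1.02 within pool 2. ALDH1A2, BNC1, UPK1B and PKHD1L1 had changes of -0.83, -2.17, -1.91 and -0.70. For UPK1B HHD replicate 2 stood at 97.0 CPM and the other HHD libraries at 31.0 CPM or less. The 20 complement and coagulation genes had a mean of -0.21 (camera adjusted p = 0.041; adjusted p = 0.80 with an estimated correlation) and 0 past the threshold adjusted over the list alone. By list score it was -0.10 without HHD replicate 2 and -0.13 without WD+S replicate 5, and -0.17 within pool 1 and -0.13 within pool 2. C7 averaged 861.5 ± 297.7 CPM in WD+S and 1310 ± 567.0 CPM in HHD, and CD55, CFI and CFP had changes of -0.53, -0.86 and -0.77. HHD replicate 2 held 439.2 CPM of CFI and 62.3 CPM of CFP, against at most 134.5 and 27.2 CPM in the other HHD libraries. Cholesterol synthesis, respiratory chain and ribosomal protein genes had small positive means of 0.17, 0.17 and 0.13 (camera adjusted p = 0.017, 0.00051 and 0.0026). With an estimated correlation these gave an adjusted p = 0.80, 0.80 and 0.83, and 0 members of the 3 lists passed when adjusted over the list alone. Without HHD replicate 3 the respiratory chain and ribosomal protein differences in list score fell to 0.05 and -0.00, and that of cholesterol synthesis was 0.27 without WD+S replicate 1. Over all libraries they were 0.14, 0.08 and 0.14 within pool 1 and 0.10, 0.20 and 0.07 within pool 2, in the order cholesterol synthesis, respiratory chain, ribosomal protein. HSD17B7, ACAT2 and SQLE had changes of 0.43 (SE 0.17), 0.45 (SE 0.18) and 0.17 (SE 0.20). COX5B and RPL18 had changes of 0.38 and 0.23.

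The second table, tested alone over 6685 genes, also gave 0 genes past the edgeR threshold in the 3 comparisons, with 547, 583 and 745 at an unadjusted p under 0.05 for WD+S against HHD+S, HHD+S against HHD and WD+S against HHD. Its 46 interferon genes had a mean log2 fold change of 1.11 in HHD+S against HHD and 1.20 in WD+S against HHD. In that table neural genes exceeded HHD by 0.72 in list score in WD+S (exact permutation p = 0.0023, adjusted p = 0.10, 7 of 8 WD+S libraries above every HHD library). Lists for MHC class II, lipogenesis, thermogenic fat, macrophages, B and plasma cells, inflammatory cytokines, smooth muscle, antioxidant defence, immediate early genes and insulin signalling passed no list test in the first table in these comparisons, with means between -0.38 and 0.30. The lowest, of B and plasma cells in WD+S against HHD, turned to 0.12 without HHD replicate 2. The highest, of MHC class II in HHD+S against HHD, came with scores of 7.70 and 8.13 in HHD+S replicates 5 and 6, against at most 6.83 in the other HHD+S libraries. Calls with the preset correlation differed between the tables. Those of the respiratory chain, ribosomal protein, mesothelial and cell cycle lists in HHD+S against HHD were lost in the second table, with camera adjusted p = 0.47, 0.26, 0.12 and 0.14. In WD+S against HHD the respiratory chain, ribosomal protein, LXR, cardiomyocyte and lysosomal lists lost theirs (camera adjusted p = 0.22, 0.22, 0.60, 0.062 and 0.082), and in WD+S against HHD+S fatty acid oxidation and the unfolded protein response did (camera adjusted p = 0.58 and 0.10). Other lists were called in the second table alone. In HHD+S against HHD these were MHC class II, with a mean of 0.47 (camera adjusted p = 0.00078), and the neural list, with 0.34 (camera adjusted p = 0.0061). In WD+S against HHD+S they were MHC class I and II, with -0.25 and -0.26 (camera adjusted p = 0.011 and 0.015), B and plasma cells, with -0.28 (camera adjusted p = 0.023), and cell cycle, with 0.29 (camera adjusted p = 0.018). MHC class I also passed in WD+S against HHD, with 0.47 (camera adjusted p = 0.0036). Each had an adjusted p = 0.81 with an estimated correlation. Most leaned on few libraries. In WD+S against HHD+S the scores of MHC class I, MHC class II and B and plasma cells in that table differed by -0.02, -0.04 and -0.12 without HHD+S replicate 6, and by -0.07, -0.13 and -0.18 without replicate 5. MHC class I also moved, to -0.39, without HHD+S replicate 1. In HHD+S against HHD, MHC class II fell to 0.25 without HHD+S replicate 6 and the neural list to 0.22 without HHD replicate 1. All but MHC class I in WD+S against HHD (0.32 within pool 1, 0.64 within pool 2) also turned between the pools. In WD+S against HHD+S the scores of MHC class I and II, B and plasma cells and cell cycle differed by 0.13, 0.19, 0.21 and 0.62 within pool 1 and by -1.14, -1.16, -1.09 and -0.29 within pool 2. In HHD+S against HHD the differences were -0.10 and 1.62 for MHC class II and 0.60 and -0.19 for the neural list.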

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

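All tests of explanations in this part were chosen after the results were seen, and so were the bounds of p used to leave a question open. A library standing far from the rest of its group was looked for in 459 groups over 153 results, as the gap to its nearest neighbour over the range of the group. There were 37 such cases. Chance alone gives about 1 in 20 groups, or 22.95 here. List scores stand beside their own members in this count, so cases repeat each other and the excess cannot be judged. A gap to the nearest neighbour also misses libraries that stand apart together, as HHD+S replicates 5 and 6 do in interferon score.

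HHD replicate 3 stood apart 9 times, each time low: the ribosomal protein score (gap over range 0.859), the respiratory chain score (0.736), NDUFB8 (0.816), COX6A1 (0.796), RPL35 (0.778), COX5B (0.696), NDUFAB1 (0.682), ABCG1 (0.672) and PSME2 (0.631). WD+S replicate 1 stood apart 8 times. It was low in the cholesterol synthesis score (0.618), SQLE (0.683), FDPS (0.638), ADD2 (0.634) and NCAM1 (0.572), and high in LEP (0.739), the B and plasma cell score (0.635) and PLTP (0.607). HHD replicate 2 was low in the insulin signalling score (0.764) and high in the cell cycle score (0.719), CD2 (0.716), TOP2A (0.690) and the B and plasma cell score (0.662). HHD+S replicate 3 was low in LEP (0.838) and high in the mesothelial score (0.649), and HHD+S replicate 1 was low in ANKRD6 (0.714). HHD+S replicate 6 was high in BCAS4 (0.686), CFP (0.634) and the antioxidant score (0.634). HHD replicate 4 was low in DPYSL3_2 (0.649) and high in CD8A (0.635), HHD replicate 6 was low in ICAM2 (0.681) and high in CDH19 (0.685), and HHD replicate 1 was low in TM7SF2 (0.630). WD+S replicate 7 was high in RPL14 (0.571) and in the ribosomal protein score (0.551), WD+S replicate 4 was high in the cell cycle score (0.532) and WD+S replicate 5 was low in the unfolded protein response score (0.532).

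HHD replicates 3 and 5 carried both XIST and Y-linked reads. An extra X chromosome is argued against, since the lower of the XIST and Y-linked levels was 30.4% and 13.9% of the median of the other libraries. Index misassignment at the rate of the other libraries is argued against as well, because the Y-linked CPM were 390.3 and 93.3 times the highest in the other XIST libraries. A candidate explanation that stays open is RNA or libraries of 2 animals mixed, for which the XIST and Y-linked shares summed to 88.7% and 108.9%, inside the 79.0% to 126% that XIST alone covers in single libraries. Chimerism between littermates, which the labels cannot address, was not tested.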

How the results depend on the processing

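Fits without named pairs of libraries, within pools for the interferon list, with the file-name code as a term, with robust dispersion and by exact permutation, and list scores without each library, were chosen after the data were seen. Of 91 alternative counts of genes 80 were 0, like the edgeR count, and 11 were above it. DESeq2 called 10 genes for WD+S against HHD+S, 11 for HHD+S against HHD and 81 for WD+S against HHD, and limma-voom 4 for the first. Fits of only the groups compared called 1 gene for WD+S against HHD+S (ABCA1_1) and 1 for WD+S against HHD (RSAD2), and fits within pool 1 called 1 and 14. Leaving out one library gave 0 to 1 genes for WD+S against HHD+S (1, MFNG, without HHD+S replicate 2), 0 for HHD+S against HHD and 0 to 22 for WD+S against HHD (22 without WD+S replicate 1, 14 without HHD replicate 6). The cause was not tested. At an unadjusted p under 0.05 edgeR gave 988, 960 and 1299 genes for WD+S against HHD+S, HHD+S against HHD and WD+S against HHD.

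The interferon list had 82 alternatives, of which 69 kept the side of the threshold, 7 of these with the direction turned while not called. For the interferon list HHD+S vs HHD the mean of 1.03 lost its call with an estimated correlation (adjusted p = 0.66), with fry (0.48) and by exact permutation (0.23), and for the interferon list WD+S vs HHD the mean of 1.13 did so with 0.66, 0.40 and 0.14. The estimated correlation between members was 0.86. Over the other alternatives of these comparisons p ran from 1.5e-39 to 0.012, the latter without HHD+S replicates 5 and 6, where the mean for HHD+S against HHD was 0.22. These p were adjusted, except that the permutation of the list score within pools entered with an unadjusted p. The camera tests among them kept the preset correlation of 0.01, far below the estimated 0.86. For each of these comparisons at least 1 other split of the libraries gave this list a stronger camera result with that setting. Calls kept or gained with the preset correlation, and the count of 69, therefore do not measure how firm the interferon result is. Leaving out one library gave means of 0.70 to 1.22 and 0.90 to 1.26. For the interferon list WD+S vs HHD+S the mean of 0.09 became 0.35 without the 3 libraries marked B, 0.91 without HHD+S replicates 5 and 6 and 0.72 within pool 1, each past the threshold. It reversed to -0.26 without WD+S replicates 7 and 8 and to -1.55 within pool 2. Leaving out one library gave -0.14 to 0.43, past the threshold without HHD+S replicate 5 (0.42) or 6 (0.43). The cause was not tested. Among the other lists 109 of 162 alternatives lost the call and 53 kept it, and of 1885 for named genes 1842 kept the side of the threshold, 27 of these with the direction turned, and 43 came to pass. No paired analysis was possible because the labels give no litter or other link between animals of different groups. Libraries of 2749337 to 6543337 counts limit what can be seen at low levels.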

Other observations

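All tests of explanations in this part were chosen after the results were seen, and so were the bounds of p used to leave a question open.

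The interferon score was higher on average in WD+S than in HHD in both pools, and in HHD+S mainly in 2 libraries of pool 2. The WD+S rise in pool 2 was also uneven. Replicates 7 and 8 scored 6.22 and 7.34, but replicates 5 and 6 scored 5.26 and 4.72, beside 4.68 and 4.64 in HHD. WD+S replicates 7 and 8 and HHD+S replicate 5 carry preparation code C3, and HHD+S replicate 6 carries C4. HHD replicate 5 of pool 2 also carries C3 and scored 4.68. HHD libraries of pool 2 exceeded those of pool 1 by 0.11 (SE 0.07) in interferon score, while HHD+S libraries did so by 2.43 (SE 0.08). A rise with pool 2 as large as in HHD+S was thus not seen in HHD. Each of these gaps rests on 2 libraries of pool 2. Their contrast is the one permuted below (exact permutation p = 0.058), where only 225 arrangements exist. A pool effect on every library is therefore not settled. Lymphocytes, among other immune cells, may contribute in HHD+S, where the T and NK cell score was higher in pool 2 by 2.62 (SE 0.26). For WD+S against HHD the score was set against the ratio of T and NK cell to interferon score seen between the pools in HHD+S. In pool 1 it differed by -0.21 (SE 0.38) where that ratio gives 1.07. In pool 2 it differed by 0.46 (SE 0.45) where that ratio gives 1.32, which leaves this open there. The ratio rests on HHD+S replicates 5 and 6 and need not hold in WD+S. Whether the change has one size in both pools cannot be told apart from a change that differs, with gaps between the pools of -2.08 for WD+S against HHD+S (exact permutation p = 0.072) and 2.32 for HHD+S against HHD (exact permutation p = 0.058), whereas for WD+S against HHD the gap was 0.23 (exact permutation p = 0.75). An effect of diet and drug together stays open and was not tested.

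The neural list had a higher mean in WD+S. Heart muscle taken with the fat is argued against as the whole cause, since with the cardiomyocyte score as a covariate the neural difference was 0.58 (SE 0.25) against HHD+S and 0.75 (SE 0.25) against HHD, beside 0.58 (SE 0.21) and 0.72 (SE 0.21) without it. A lower share of fat cells is argued against too, because the neural score exceeded 4 of 5 other cell lists in its difference from HHD (exact permutation p under 0.05 each). A larger share of nerve, with neurons and glia together, could not be told apart from a change in neurons: the glial score differed by 0.14 (SE 0.25) against HHD+S, where the neuronal score differed by 0.79 (SE 0.28; exact permutation p = 0.069), and by 0.53 (SE 0.20) against HHD, where the neuronal score differed by 0.87 (SE 0.27; exact permutation p = 0.20). An effect of the diet on nerve and a different place of dissection stay open, and neither was tested.

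In 100 splits of the same libraries, the real one included, a mean interferon fold change as large as 1.03 for HHD+S against HHD came up 1 time (highest other 1.02), and one as large as 1.13 for WD+S against HHD 1 time (highest other 1.01). By these shares alone chance can be excluded, but the splits ignore the pool and are not adjusted for their number. Adjusted over all list tests the exact permutation p was 0.23 and 0.14, so chance is left open for both. For WD+S against HHD+S, 93 splits gave at least the real 0.09 (highest other 1.17), so chance cannot be excluded. Counts of genes at an unadjusted p under 0.05 were as large in 4 splits for WD+S against HHD (1299, highest other 1687), in 9 for WD+S against HHD+S (988, highest other 1571) and in 33 for HHD+S against HHD (960, highest other 2777). For the latter 2 chance cannot be excluded, and for WD+S against HHD it is left open, as 1 of 12 shares with no adjustment. For the genes past the edgeR threshold the splits are void, because every split gives at least the real count of 0 (100 of 100 in each comparison). The highest other edgeR counts were 9, 4 and 1 for WD+S against HHD+S, HHD+S against HHD and WD+S against HHD. The DESeq2 counts of 10, 11 and 81 cannot be set against these, because DESeq2 was not run on the splits. Lists called by camera with the preset correlation numbered 8, 9 and 12 in the same order, and 63, 52 and 34 of 100 splits gave as many (highest other 18, 19 and 19), so chance cannot be excluded for the number of lists called.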
